A study of Mus musculus with 54 samples.

How the data were processed

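RNA was measured by sequencing in 54 libraries. Of these, 40 came from small intestine, large intestine, spleen and thymus of C57B6 mice, with 10 libraries per tissue. The other 14 came from NIH3T3, an established line of mouse embryonic fibroblasts. Per the labels, mice and cells received 10 Gy of gamma radiation, and the library at 0 h of each system was not treated. Each tissue had 1 library at 0 h, at every hour from 1 to 8 h and at 24 h. NIH3T3 also had 1 at every hour from 9 to 12 h. Per the labels, organs were taken from euthanized mice, kept in RNAlater and ground in Trizol. Polyadenylated RNA went into unstranded Illumina TruSeq libraries.

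Per the labels, the authors aligned reads to the mouse genome build mm10 with TopHat2 2.1.0 and estimated transcript levels with Cufflinks 2.1.1. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, for 13611 genes named by symbol. How these genes were chosen, and whether libraries were scaled further, is not given in the sources used here. FPKM is a share of all mapped fragments, so a change in a few abundant transcripts moves other values the opposite way. Of the symbols, 13027 matched a gene in the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, from which positions were taken.

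Total fragment counts are not given in the sources used here, so no counting interval was computed for single values. Relative depth within a system was estimated from the smallest steps between low FPKM values. The deepest library held 1.68 times the fragments of the shallowest in small intestine, 2.08 in large intestine, 2.42 in spleen, 3.56 in thymus and 1.90 in NIH3T3. Pairs of libraries agreed poorly in these estimates in small intestine (0% within 0.05 at 1 h, 11.1% at 5 h and 6 h), spleen (22.2% at 5 h) and thymus (11.1% at 4 h and 24 h), so the ratios are rough. The median standard deviation of log2 values within a time window was 0.19 in small intestine, 0.23 in large intestine, 0.21 in spleen, 0.19 in thymus and 0.14 in NIH3T3.

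Libraries were grouped by system and time window. The windows were 0 h (n = 1), 1 to 2 h (n = 2), 3 to 5 h (n = 3), 6 to 8 h (n = 3), 24 h (n = 1) and, in NIH3T3, 9 to 12 h (n = 4). Within a window, libraries of neighbouring hours served as replicates. The labels do not say that libraries of different hours come from separate animals or cultures, so p-values measure the spread between these libraries. The windows, comparisons, gene lists, tests, thresholds and most alternatives were fixed before the data were examined.

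Gene-level tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Each window of each system had its own mean, and the prior variance followed a trend over expression. The 40 tissue libraries shared 1 fit with 20 residual degrees of freedom, and NIH3T3 had its own fit with 8. Genes with a mean FPKM of at least 1 in the system were tested. Calls were made at a Benjamini-Hochberg adjusted p below 0.05, two-sided, with no fold threshold. Changes are log2 fold changes of FPKM + 1 with the standard error from limma unless FPKM is named. FPKM means are given with the standard deviation over the libraries of a window.

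In each system, the mean of the 8 libraries at 1 to 8 h was compared with 0 h, the libraries at 6 to 8 h with those at 1 to 5 h, and 24 h with 0 h. In NIH3T3, 9 to 12 h was also compared with 1 to 5 h, and a rhythm with a period of 5 h was tested with a limma F-test of cosine and sine terms beside linear and quadratic time. The mean change in spleen and thymus minus the mean change in the intestines was tested in the tissue fit, over genes with a mean FPKM of at least 1 in all 4 tissues. The libraries at 0 h and 24 h are single, so these contrasts assume that they vary like the libraries within windows. For 24 h against 0 h there is no replicate check, and list medians are given with their percentile among 10000 random lists of matched size and expression.

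A total of 37 gene lists was fixed, covering p53 targets, pathways, and markers of the cell types that the tissues or their neighbours hold. The p53 targets formed 3 lists, for arrest and feedback, for apoptosis, and for repair and metabolism, and their union is called the p53 target list. A list was called by fry, the directional rotation test of limma, adjusted over the lists of a comparison. The competitive test camera was run with a preset correlation of 0.01 and with a correlation estimated from the data. Where a call was lost with the estimated correlation, that adjusted p is printed. For each list the members past the threshold are counted over all genes tested and adjusted over the list alone.

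Genes were named by a fixed rule. For 1 to 8 h against 0 h these are the 6 highest and 6 lowest log2 fold changes among genes past the threshold with all 8 irradiated libraries on the same side of 0 h. For the other comparisons they are the 5 highest and 5 lowest, and for the later windows all later libraries had to lie outside the earlier range. Unnamed gene models, microRNA and small nucleolar RNA genes, and immunoglobulin and T cell receptor segments were left out. A panel of 12 genes of the p53 pathway was followed in every system, and each list is described by up to 4 members with the smallest adjusted p. The values of some members are not reported here. Some genes were listed near 0, below 0.05 FPKM, in a library of a system where their median was at least 2. This is stated where such a library enters the comparison named.

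Simulated data held log2 changes of 1 and 2, each in 100 genes per comparison. For 1 to 8 h against 0 h, changes of 1 were recovered in 59% to 64% of genes in the tissues and 83% in NIH3T3. All 16 lists of 50 changed genes, but also 2 of 16 unchanged lists, passed fry at an unadjusted p below 0.05. Lists with smaller changes were not simulated.

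The alternatives were another pseudocount, no filter on low values, median-of-ratios scaling, quantile normalization, a robust prior variance without trend, a separate fit per tissue, other window borders, a 2-fold threshold, a spline over time, other rhythm periods, time point as a random block, the fit without the 24 h libraries, and leaving out each irradiated library in turn. Chosen after seeing the data were the fits without libraries that held transcripts of another organ, a subtraction of the small intestine share from the 24 h thymus library, and a test without the genes listed near 0.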

Results

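The series followed messenger RNA after 10 Gy of gamma radiation in small intestine, large intestine, spleen and thymus of C57B6 mice and in the fibroblast line NIH3T3. Its title links p53, the transcription factor activated by DNA damage, to the radiation sensitivity of tissues. Comparisons ask what changed over the first 8 h, within them and by 24 h, and whether spleen and thymus differed from the intestines. Each tissue had 10 libraries and NIH3T3 14, with 1 per time point. Only 0 h was unirradiated, so effects of time, handling or culture cannot be told from radiation. Changes are log2 fold changes of FPKM + 1 ± SE.

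Several libraries carried transcripts of another organ. The 24 h thymus library held Fabp2, a fatty acid binding protein of the small intestine, at 2351 FPKM, against a median of 0.897 in the other thymus libraries. It also held the brush border enzymes Sis and Lct at 312 and 180 FPKM. Over 312 genes of the small intestine, its values had a median ratio of 11.2% to the 24 h small intestine library. The 2 h large intestine library held Sis at 1092 and Lct at 523 FPKM, and 84 small intestine genes had a median ratio of 38.1% to the 2 h small intestine library. The 6 h spleen library held digestive enzymes of the pancreas, with Pnlip at 7419, Ctrb1 at 14226 and Prss2 at 9880 FPKM. The 1 h large intestine library was low in the epithelial genes Muc2 (378 FPKM, median of the others 1352) and Alpi (0.729 and 38.3). The 0 h large intestine library held the keratinocyte genes Krtdap at 16.2 and Krt10 at 7.77 FPKM and the ileal bile acid binding protein Fabp6 at 160 FPKM.

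**Figure D1:**
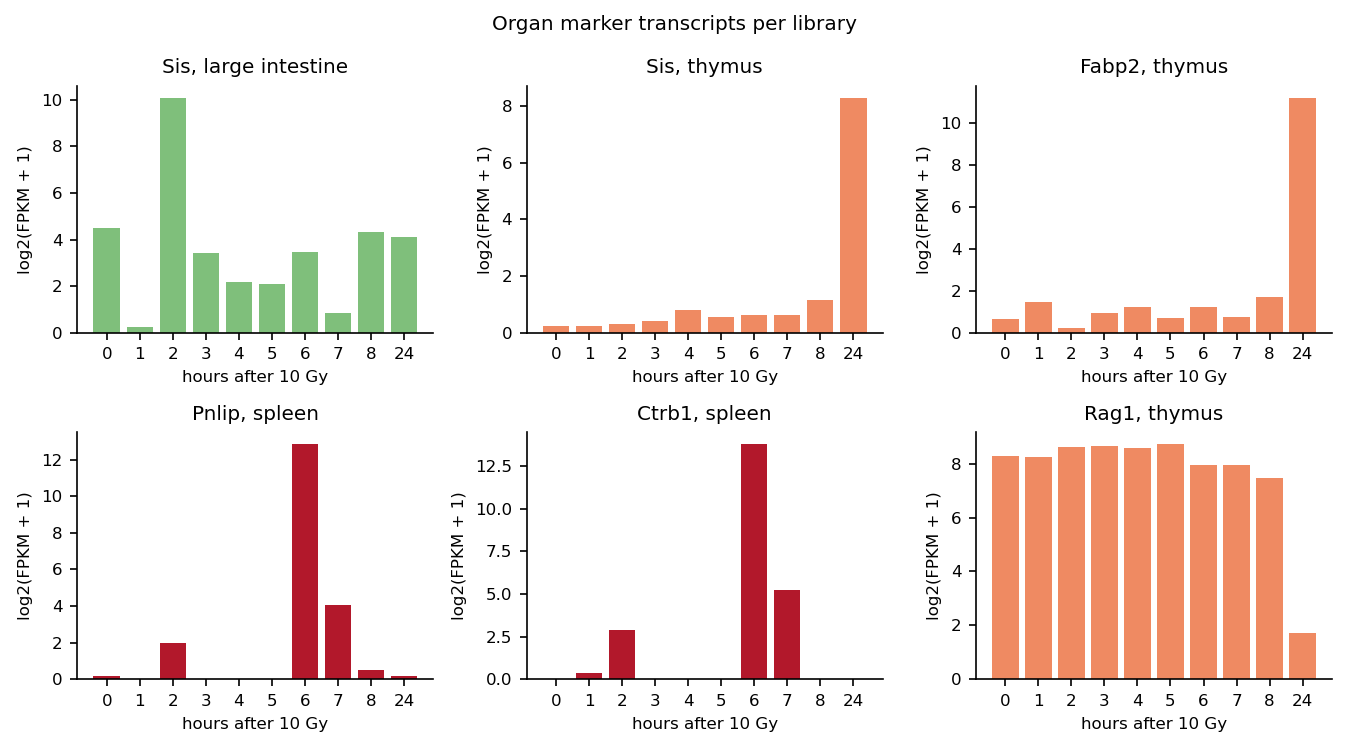
Bars show log2(FPKM + 1) of transcripts of another organ in each library, by hours after irradiation, and of the thymocyte gene Rag1 in thymus. Pnlip reached 7419 FPKM in spleen at 6 h, Fabp2 reached 2351 FPKM in thymus at 24 h, and Rag1 stood at 2.27 FPKM in that thymus library.

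Targets of p53 rose in every tissue over the first 8 h. A set of 14 genes rose in all 4 tissues, namely Aen, Bax, Bbc3, Ccng1, Ddias, Ddit4, Ddit4l, Eda2r, Mgmt, Phlda3, Plk2, Rps27l, Thyn1 and Trp53inp1. Of these, Bbc3, Ccng1, Ddias, Eda2r and Trp53inp1 also rose in NIH3T3. No gene fell in all 4 tissues (0 by limma). Cdkn1a, which encodes the cell cycle inhibitor p21, lies on chromosome 17 (29090979 to 29100722, GRCm38.p6) and stood at 4.45 FPKM in spleen and 9.88 in thymus at 0 h. At 1 to 8 h it averaged 241 ± 56 in spleen and 220 ± 87 in thymus (SD, n = 8). Its level at 0 h was 199 FPKM in small intestine and 169 in large intestine. Ccng1, which encodes cyclin G1, started at 37.6, 44.7, 39.6 and 32.9 FPKM in small intestine, large intestine, spleen and thymus. Its means at 6 to 8 h were 301, 397, 284 and 267 FPKM.

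**Figure D2:**
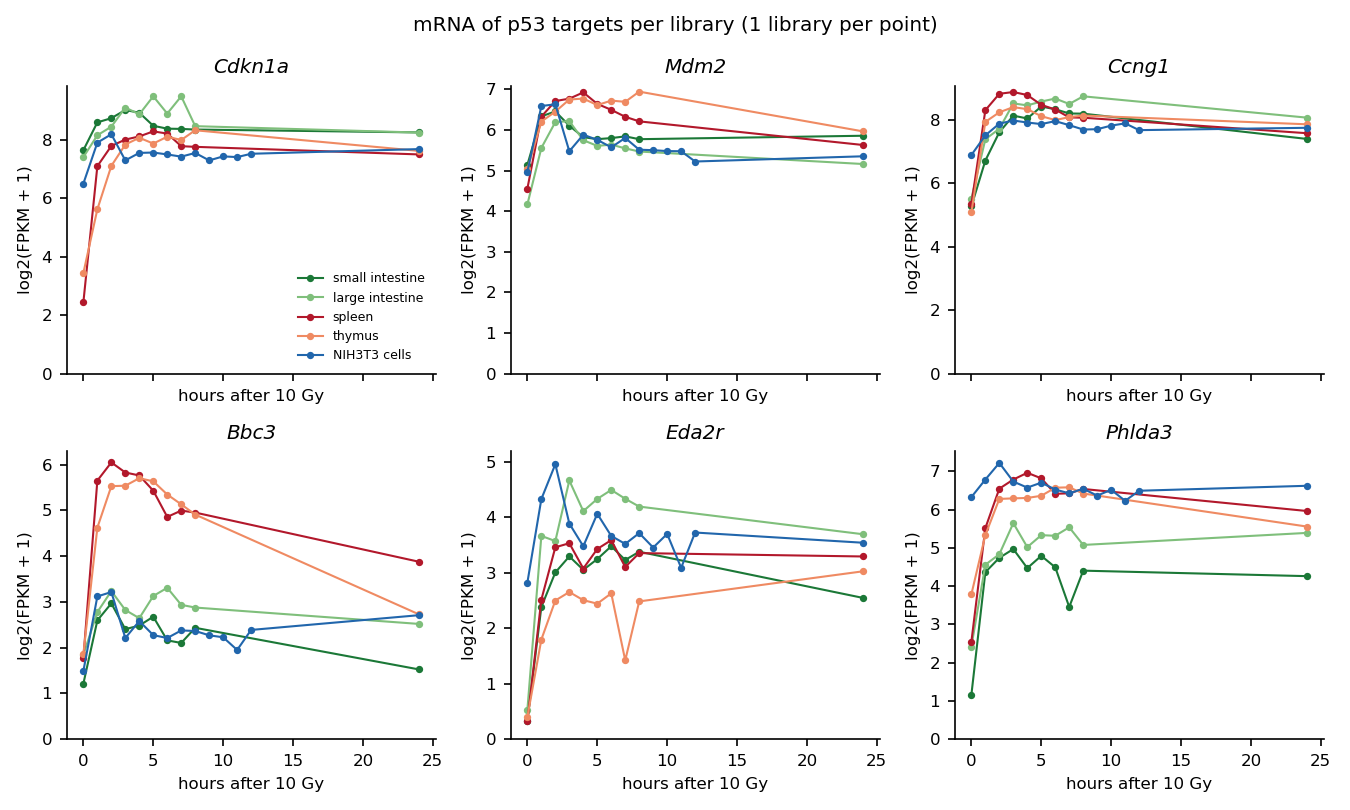
Joined points show log2(FPKM + 1) of the p53 targets Cdkn1a, Mdm2, Ccng1, Bbc3, Eda2r and Phlda3 in each library against hours after irradiation. Cdkn1a starts at 4.45 FPKM in spleen and 9.88 in thymus, below the 199 and 169 FPKM of small and large intestine.

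Genes that rose over the first 8 h were shared between systems beyond chance. Spleen and thymus shared 305 genes against 46.1 expected (Fisher's exact test p = 1.03e-193), and small and large intestine shared 17 against 0.415 (exact p = 1.75e-24). Among falling genes, spleen and thymus shared 109 against 16.2 expected (Fisher's exact p = 7.03e-62). Genes are not independent, so these p-values describe the lists only.

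**Figure D3:**
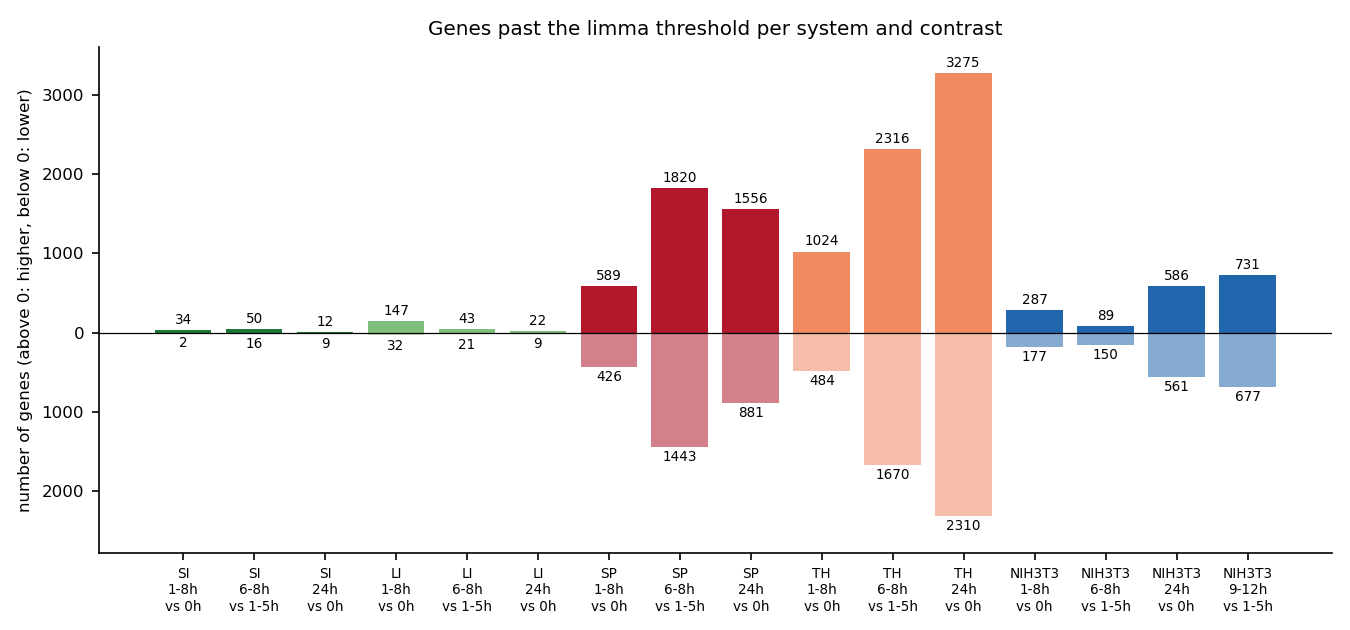
Bars give the number of genes past the threshold in small intestine (SI), large intestine (LI), spleen (SP), thymus (TH) and NIH3T3, with rising genes above 0 and falling genes below 0. For 24 h against 0 h, 5585 genes changed in thymus and 21 in small intestine.

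In small intestine over 1 to 8 h, p53 targets rose. Phlda3, an inhibitor of Akt signalling, rose by 3.30 ± 0.33 (adjusted p = 3.22e-06), from 1.23 FPKM at 0 h to 21.9 ± 6.1 (SD, n = 8). Eda2r, a member of the TNF receptor family, rose by 2.80 ± 0.34 (adjusted p = 4.81e-05), and Ccng1 by 2.68 ± 0.22 (adjusted p = 2.11e-07). The kinase gene Plk2 rose by 2.46, the nuclease gene Aen by 2.36, the DNA repair gene Mgmt by 2.01, Trp53inp1 by 1.75 and the apoptosis gene Bax by 1.53 ± 0.26 (adjusted p = 0.00452). Sesn2 rose by 1.30, and Bbc3, which encodes the cell death protein PUMA, by 1.26 ± 0.25 (adjusted p = 0.0231). Cdkn1a changed by 0.96 ± 0.36 (adjusted p = 0.528) and Mdm2, the ubiquitin ligase that degrades p53, by 0.85 ± 0.20 (adjusted p = 0.0722). Trp53 itself differed by 0.09. The highest changes by the fixed rule were those of Clec4n (3.88 ± 0.51), Cpsf1 (3.46 ± 0.35) and Mro (3.37 ± 0.42), which were listed near 0 at 0 h (0.000558, 0.0126 and 0.00124 FPKM). Rfx2 fell by 1.56 and Rab19 by 0.92.

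Of 51 tested p53 targets, 13 rose in small intestine over all genes tested and 25 adjusted over the list alone (median 0.67, fry adjusted p = 0.000472). The arrest and feedback list had 4 rising members (12 adjusted over the list alone), the apoptosis list 8 (10) and the repair and metabolism list 3 (5). Glucocorticoid response genes rose as a list of 15 (median 1.18, fry adjusted p = 0.00482), with Ddit4 up by 1.63 ± 0.33 as the single member past the threshold and 6 adjusted over the list alone. The intestinal stem cell list of 9 genes was lower (median -0.51, fry adjusted p = 0.0439), with 0 members past the limma threshold and 1 adjusted over the list alone, and adjusted p = 0.113 with an estimated correlation. Its receptor gene Lgr5 had -0.73 ± 0.20 (adjusted p = 0.157). In total 36 of 11392 genes changed, 34 up and 2 down. The count was 57 with a pseudocount of 0.1, 20 in a separate fit and 23 with other window borders.

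Between 1 to 5 h and 6 to 8 h, mitotic genes rose in small intestine. Ccnb1, which encodes cyclin B1, rose by 1.77 ± 0.27 (adjusted p = 0.0025). It stood at 3.07 FPKM at 0 h, 0.925 at 1 to 2 h, 1.42 at 3 to 5 h and 6.54 ± 1.4 (SD, n = 3) at 6 to 8 h. Hmmr rose by 1.60 ± 0.27 (adjusted p = 0.00611), the mitotic kinesin gene Kif20a by 1.57, Cdc20 by 1.49 and Cenpf by 1.11. Of 30 genes of the G2 and M phases, 12 rose, or 29 adjusted over the list alone (median 1.15, fry adjusted p = 0.0026, adjusted p = 0.0594 with an estimated correlation). The DNA repair and checkpoint list had a median of 0.28 with 0 of 20 members past the limma threshold and 0 adjusted over the list alone (fry adjusted p = 0.0446, adjusted p = 0.188 with an estimated correlation), and fry gave adjusted p = 0.129 after quantile normalization. Egfl7 rose by 1.92 ± 0.33 from below 0.05 FPKM in 4 of 5 early libraries, against 3.51 at 0 h. The chemokine gene Cxcl10 fell by 1.69 ± 0.33 and the repressor gene Bcl6 by 1.12. Cutc fell by 3.17 ± 0.35, Rpl34 by 2.88 and the lymphocyte receptor gene Cd160 by 1.71, all listed near 0 in later libraries. The p53 target list had a median of -0.07 (fry adjusted p = 0.946).

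In all, 66 genes changed between these windows in small intestine, 50 up and 16 down. The count was 2 without the 8 h library, 16 without that of 2 h, 18 without that of 6 h, 5 in a separate fit and 138 without the 2 h large intestine and 6 h spleen libraries.

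At 24 h, some p53 targets still stood above 0 h in small intestine. Phlda3 was higher by 3.10 ± 0.45 (adjusted p = 0.00142), Ccng1 by 2.13 ± 0.30 (adjusted p = 0.00142), Mgmt by 2.41 ± 0.50 (adjusted p = 0.0401) and Eda2r by 2.21. G0s2 was higher by 2.72, and the gasdermin gene Gsdmc2 was lower, at -2.77 ± 0.54 (0 FPKM at 24 h). Clec4n (4.19) and Cpsf1 (3.21) were listed near 0 at 0 h, and Cutc (-3.53), Rpain (-2.71) and Nip7 (-2.38) at 24 h, where Oaz1 (-4.92) had 0.113 FPKM. The interferon-induced gene Bst2 was higher by 2.05 ± 0.37 (adjusted p = 0.0119). The p53 target list had 6 rising members, or 15 adjusted over the list alone (median 0.55, percentile 100 among 10000 random lists, fry adjusted p = 0.107). The fry test called 0 lists, and 21 genes changed, 12 up and 9 down. The count was 46 with a pseudocount of 0.1, 10 in a separate fit, 13 with other window borders and 13 without the genes listed near 0.

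In large intestine over 1 to 8 h, p53 targets rose, and genes of DNA replication were lower. Eda2r rose by 3.64 ± 0.34 (adjusted p = 5.02e-07), Ccng1 by 2.80 ± 0.22 (adjusted p = 9.1e-08), Phlda3 by 2.74 ± 0.33 and Plk2 by 2.66. Mdm2 rose by 1.58 ± 0.20 (adjusted p = 4.2e-05), Cdkn1a by 1.46 ± 0.36 (adjusted p = 0.0375), Pmaip1 by 1.86, Bax by 1.19 and Bbc3 by 1.12. Of 51 targets 21 rose, or 35 adjusted over the list alone (median 1.08, fry adjusted p = 2.29e-05). The S phase list of 26 genes had a median of -0.72, with 4 falling, or 13 adjusted over the list alone (fry adjusted p = 0.0483, adjusted p = 0.214 with an estimated correlation). Its members include Mcm6 (-1.44 ± 0.31), Mcm5 (-1.43) and Mcm3 (-1.17), and Gins2 (-1.30).

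The NF-kB list of 11 inflammatory genes was higher in large intestine (median 0.73, fry adjusted p = 0.0171, adjusted p = 0.161 with an estimated correlation), with 1 member past the threshold, Icam1 (1.33), and 3 adjusted over the list alone. The list median was 1.78 at 1 h and 1.1 at 2 h, in the libraries with altered epithelial markers, and 0.29 to 0.51 at 3 to 8 h. The colonocyte list of 11 genes rose (median 0.74, fry adjusted p = 5.41e-05) against a 0 h library that held transcripts of other tissues, with Ceacam20 up by 1.34 ± 0.29 as 1 member past the threshold and 6 adjusted over the list alone. Lcn2 rose by 2.68, and the glucocorticoid-induced gene Ddit4 by 1.31. Other high changes were those of Ms4a10 (4.53 ± 0.92), Slc15a1 (4.06 ± 0.57, adjusted p = 0.000187), Anxa8 (3.03 ± 0.65) and Tnip3 (2.87 ± 0.53). Kbtbd4 (3.31) was listed near 0 at 0 h. Ms4a10 and Slc15a1 stood at 315 and 333 FPKM in the 2 h library with small intestine transcripts, and at 4.82 and 208 at 1 h. Krtdap (-3.86 ± 0.36), Krt10 (-1.79 ± 0.29) and Fabp6 (-3.33 ± 0.81) fell against the 0 h library that held keratinocyte and ileal transcripts.

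In large intestine 179 of 11854 genes changed over 1 to 8 h, 147 up and 32 down. The count was 508 without the 2 h library, which carried small intestine transcripts, 441 without that of 1 h and 506 without the 2 h large intestine and 6 h spleen libraries. It was 118 with a 2-fold threshold, 17 in a separate fit, 88 with other window borders and 1 with a spline over time.

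From 1 to 5 h to 6 to 8 h, some inflammatory genes fell in large intestine. Nox1, an NADPH oxidase of the colon, fell by 2.44 ± 0.40 (adjusted p = 0.00392), from 34.9 FPKM at 1 to 2 h and 8.15 at 3 to 5 h to 1.39 at 6 to 8 h. The adhesion gene Icam1 fell by 1.26 ± 0.23 (adjusted p = 0.00817), Fosl1 by 1.47 and Birc3 by 0.61. The NF-kB list had 2 falling members (median -0.60, fry adjusted p = 0.0209, adjusted p = 0.243 with an estimated correlation), and adjusted over the list alone 6 fell and 1 rose. This fall lies mostly in the 1 h and 2 h libraries. The heat shock list of 13 had 1 falling member, Hsph1 (-1.03 ± 0.23), and adjusted over the list alone 10 fell and 1 rose (median -0.47, fry adjusted p = 0.00331, adjusted p = 0.0719 with an estimated correlation). The detoxification gene Ephx1, a p53 target, rose by 1.37 ± 0.18 (adjusted p = 0.0014), from 19.1 FPKM at 0 h to 204 ± 18 at 6 to 8 h (SD, n = 3).

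Mitotic genes were higher at 6 to 8 h in large intestine as a list of 27, with 1 member past the threshold, Hmmr (1.21 ± 0.27), and 23 adjusted over the list alone (median 0.87, fry adjusted p = 0.0209, adjusted p = 0.243 with an estimated correlation). The colonocyte list (median 0.21, fry adjusted p = 0.0186), the goblet cell list (median 0.39, fry adjusted p = 0.0397) and the p53 repair list (median 0.09, fry adjusted p = 0.0397) had 1, 0 and 2 members past the limma threshold, and 2, 4 and 2 adjusted over the list alone. With an estimated correlation their adjusted p was 0.243, 0.243 and 0.405. The union of p53 targets had a median of 0.14 (fry adjusted p = 0.44). Exoc4 rose by 1.69 and Grp by 1.21. In all 64 genes changed, 43 up and 21 down, and 12 of 56 splits of the same libraries gave as many, up to 543. The count was 531 without the 1 h library, 23, 21 and 38 without those of 6 h, 7 h and 8 h, and 0 in a separate fit by limma. It was 6 with a pseudocount of 0.1 and 16 with other window borders.

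At 24 h, large intestine held p53 targets above 0 h. Eda2r was higher by 3.16 ± 0.46 (adjusted p = 0.000583), Ephx1 by 3.12 ± 0.35 (adjusted p = 3.28e-05), Phlda3 by 2.97, Ccng1 by 2.55 ± 0.30 and Plk2 by 2.5. The p53 target list had 7 rising members, or 23 adjusted over the list alone (median 0.87, percentile 100, fry adjusted p = 0.00185), and fry gave adjusted p = 0.0688 with other window borders. The colonocyte list rose (median 1.08, percentile 100, fry adjusted p = 0.00185), with 0 members past the limma threshold and 2 adjusted over the list alone. Tk1 was lower (-2.06 ± 0.38, adjusted p = 0.0107), as was the G protein regulator Rgs17 (-2.02 ± 0.23, adjusted p = 3.28e-05) and Aldh3b2 (-2.32). Krtdap (-3.49), Krt10 (-2.30) and the colonocyte list again stand against the 0 h library with keratinocyte transcripts, and Kbtbd4 (3.28) was listed near 0 there. In all 31 genes changed, 22 up and 9 down. The count was 91 without the 1 h library, 95 without the 2 h large intestine and 6 h spleen libraries, and 2 in a separate fit.

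In spleen over 1 to 8 h, p53 targets and inflammatory genes rose and B cell genes fell. Cdkn1a rose by 5.44 ± 0.36 (adjusted p = 1.4e-09), the cytokine gene Gdf15 by 5.23 ± 0.61 (adjusted p = 7.32e-06), Phlda3 by 3.95 ± 0.33 and Tnfsf4 by 3.95 ± 0.34. Bbc3 rose by 3.66 ± 0.25 (adjusted p = 2.42e-09), from 2.42 FPKM at 0 h to 57.1 at 1 to 2 h. Ccng1 rose by 3.12, Eda2r by 2.93, Sesn2 by 2.75, Pmaip1 by 2.47, Bax by 2.09, the death receptor gene Fas by 2.05, Mdm2 by 2.0 ± 0.20 and Trp53inp1 by 1.86. Trp53 differed by 0.03. Of 51 p53 targets, 34 rose and 1 fell, or 38 and 3 adjusted over the list alone (median 1.86, fry adjusted p = 5.4e-08). Timp1 (4.92) was listed at 0 FPKM at 0 h and averaged 116 FPKM at 6 to 8 h.

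B cell markers fell in spleen. Of 16 tested, 12 fell, or 13 adjusted over the list alone (median -1.26, fry adjusted p = 2.08e-06). The kinase gene Blk fell by 1.77 ± 0.21 (adjusted p = 7.32e-06), Fcrla by 1.90, Fcmr by 1.68 and the B cell receptor subunit gene Cd79a by 1.93 ± 0.33 (adjusted p = 0.000606). Cd22 fell by 2.67 ± 0.63 and H2-Ob, which regulates antigen loading in B cells, by 2.13 ± 0.27. T cell markers had 4 of 18 members falling, and 4 adjusted over the list alone, with Cd2 at -1.67 (median -0.55, fry adjusted p = 0.00888, adjusted p = 0.166 with an estimated correlation). Erythroid genes had 5 of 18 falling, and 5 adjusted over the list alone (median -0.61, fry adjusted p = 0.0213, adjusted p = 0.251 with an estimated correlation). Among these the carbonic anhydrase gene Car1 fell by 5.56 ± 0.89, and the transcription factor genes Klf1 and Gata1 by 1.95 and 1.39.

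Proliferation genes were lower in spleen over 1 to 8 h. The S phase list had 12 of 28 members falling, or 21 adjusted over the list alone (median -0.88, fry adjusted p = 0.00279, adjusted p = 0.133 with an estimated correlation), with Ccne1 at -1.66 and Mcm7 at -1.25. The G2 and M list had 5 of 30 falling, or 24 adjusted over the list alone (median -1.13, fry adjusted p = 0.021, adjusted p = 0.244 with an estimated correlation), with Plk1 at -1.2 and Bub1 at -1.22. The NF-kB list had 11 of 19 rising, or 12 adjusted over the list alone (median 1.72, fry adjusted p = 0.000318, adjusted p = 0.0649 with an estimated correlation), with Il1b up by 2.82, Tnfaip3 by 1.77 and Icam1 by 1.61. The chemokine gene Ccl2 rose by 3.98 ± 0.80. Neutrophil genes had 5 of 13 rising, or 7 adjusted over the list alone (median 1.08, fry adjusted p = 0.00157, adjusted p = 0.15 with an estimated correlation), with the receptor gene Csf3r up by 2.25 ± 0.26, Mmp8 by 2.32 and Cxcr2 by 1.91. Glucocorticoid response genes had 4 of 15 rising, or 10 adjusted over the list alone (median 1.2, fry adjusted p = 0.000183, adjusted p = 0.0527 with an estimated correlation), with Ddit4 up by 2.28 and Errfi1 by 2.22. Macrophage genes had 4 of 17 rising, or 5 adjusted over the list alone (median 0.54, fry adjusted p = 0.0175, adjusted p = 0.252 with an estimated correlation), with Cd14 up by 2.03 and Marco by 1.58.

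In spleen 1015 of 11791 genes changed over 1 to 8 h, 589 up and 426 down. The share that rose was 58.0%, and 48.0% after quantile normalization. The count was 546 in a separate fit, 502 with a 2-fold threshold and 4099 with a spline over time.

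Between 1 to 5 h and 6 to 8 h, B cell genes fell further in spleen and neutrophil genes rose. Of 16 B cell markers 15 fell, or 16 adjusted over the list alone (median -1.5, fry adjusted p = 1.93e-09). Fcer2a fell by 3.06 ± 0.35 (adjusted p = 1.55e-06), Cxcr5 by 2.66 ± 0.22 (adjusted p = 1.14e-08), Pax5 by 2.17 ± 0.22 and Ms4a1 by 2.07. T cell genes had 6 of 18 falling, or 7 adjusted over the list alone, with Cd8b1 at -1.57 (median -0.37, fry adjusted p = 0.0034, adjusted p = 0.38 with an estimated correlation). Neutrophil genes had 8 of 13 rising, or 9 adjusted over the list alone (median 2.66, fry adjusted p = 9.1e-09, adjusted p = 0.0508 with an estimated correlation). The collagenase gene Mmp8 rose by 3.84 ± 0.25 (adjusted p = 5.03e-10), Cxcr2 by 2.66 and Csf3r by 2.53, which reached 90.4 FPKM. The chemokine gene Cxcl5 rose by 4.02 ± 0.55 (adjusted p = 1.53e-05), Mmp3 by 3.87 and Slfn4 by 4.50 ± 0.42 (adjusted p = 1e-07).

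Macrophage genes had 11 of 17 members rising at 6 to 8 h in spleen, or 13 adjusted over the list alone (median 0.59, fry adjusted p = 0.000386), with Cd5l up by 1.52 and Cd68 by 1.05. Plasma cell genes had 5 of 8 rising, or 6 adjusted over the list alone (median 0.69, fry adjusted p = 0.000702), with Xbp1 up by 1.34 ± 0.15 and Jchain by 0.83. Both lists had adjusted p = 0.38 with an estimated correlation. All 12 pancreatic acinar genes rose (median 5.08, fry adjusted p = 0.00692, adjusted p = 0.537 with an estimated correlation), among them Cela2a by 6.0, Prss2 by 5.54, Pnlip by 5.4 and Cela1 by 4.40 ± 1.09, all 12 also adjusted over the list alone. These stand with the 6 h library, in which Cela2a was listed at 16403 FPKM, and Pnlip stood at 15.4 FPKM at 7 h. The S phase list had 9 of 28 falling, and 9 adjusted over the list alone, with Cdt1 at -1.01 (median -0.49, fry adjusted p = 0.0281, adjusted p = 0.537 with an estimated correlation). The p53 target list showed 3 members up and 6 down (median -0.14, fry adjusted p = 0.479). Bbc3 fell by 0.81 ± 0.18, Ccng1 by 0.49 and Trp53 by 0.77 ± 0.13 (adjusted p = 0.000126). In total 3263 genes changed, 1820 up and 1443 down, a rising share of 55.8%, and 44.5% after quantile normalization. The count was 2123 without the 8 h library, and without the 1 h library the p53 list had a median of -0.32 (fry adjusted p = 0.0447).

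At 24 h in spleen, erythroid and lymphocyte genes were far below 0 h. Of 18 erythroid genes 17 fell, and adjusted over the list alone 17 fell and 1 rose (median -4.39, percentile 0, fry adjusted p = 2.23e-07). Slc4a1 went from 79.2 to 0.0610 FPKM (-6.24 ± 0.49, adjusted p = 5.63e-08), Alas2 had -6.28 ± 0.74 and Car1 -6.96. Hbb-bs (-8.78) was listed near 0 at 24 h. All 16 B cell markers fell, also adjusted over the list alone (median -2.96, percentile 0, fry adjusted p = 4.26e-09), with Pax5 at -3.57. Of 18 T cell markers 17 fell, with 1 rising adjusted over the list alone (median -1.71, percentile 0, fry adjusted p = 3.93e-07), with Cd8b1 at -4.75 and Lef1 at -3.12. The S phase list (17 of 28 falling, median -1.39, fry adjusted p = 0.00143) and the G2 and M list (19 of 30 falling, median -1.65, fry adjusted p = 0.0044) had adjusted p = 0.196 and 0.252 with an estimated correlation. Adjusted over the list alone, 23 and 25 fell and 0 and 1 rose, among the falling Mcm7 (-1.93) and Ccna2 (-2.80).

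Interferon response genes were higher at 24 h in spleen, with 22 of 26 rising, or 23 adjusted over the list alone (median 2.40, percentile 100, fry adjusted p = 0.00138, adjusted p = 0.252 with an estimated correlation). Irf7 went from 43.3 to 400 FPKM (3.18 ± 0.53, adjusted p = 0.000204) and Bst2 rose by 2.43. Macrophage genes had 14 of 17 rising, or 16 adjusted over the list alone (median 1.79, percentile 100, fry adjusted p = 5.63e-07), with Cd68 up by 2.29 and C1qc by 1.83. Fibroblast genes had 6 of 8 rising, or 7 adjusted over the list alone (median 1.85, percentile 100, fry adjusted p = 0.00138, adjusted p = 0.252 with an estimated correlation), with Col3a1 up by 2.38 ± 0.59 and Dcn by 2.12. Cdkn1a was higher by 5.05 ± 0.47 (adjusted p = 3.8e-07), Phlda3 by 3.42, Bbc3 by 2.1 and Mdm2 by 1.07, while Trp53 was lower (-0.69, adjusted p = 0.0458). The p53 target list had 24 rising and 2 falling members, or 27 and 2 adjusted over the list alone (median 1.07, percentile 100, fry adjusted p = 0.00138, adjusted p = 0.263 with an estimated correlation). Slfn4 rose by 5.12 ± 0.82 and Gpnmb by 3.78. In all 2437 genes changed, 1556 up and 881 down, a rising share of 63.8%, and 49.4% after quantile normalization, which moved the median of all genes from 0.09 to -0.03.

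In thymus over 1 to 8 h, p53 targets rose together with chemokine and immediate early genes. Gdf15 rose by 5.92 ± 0.61 (adjusted p = 9.46e-07), Cdkn1a by 4.17 ± 0.36 (adjusted p = 4.47e-08), Bbc3 by 3.44 ± 0.25 (adjusted p = 6.31e-09), Pmaip1 by 3.16, Ccng1 by 3.07, Sesn2 by 2.59 and Phlda3 by 2.48. Bax rose by 2.25 ± 0.26, Eda2r by 1.90 and Mdm2 by 1.61 ± 0.20. Trp53 had -0.35 (adjusted p = 0.232). Of 51 p53 targets 36 rose, and adjusted over the list alone 40 rose and 1 fell (median 1.60, fry adjusted p = 9.1e-08). The chemokine genes Ccl7 and Ccl2 rose by 5.70 ± 0.81 and 4.98 ± 0.80, Cyr61 and Thbs1 by 5.25 ± 0.94 and 4.97 ± 0.47, and Tnf, listed near 0 at 0 h, by 4.99 ± 0.85.

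The NF-kB list had 13 of 20 members rising in thymus, or 18 adjusted over the list alone (median 1.71, fry adjusted p = 5.89e-06), with Il1b up by 4.13 ± 0.58, Ccl3 by 4.50, Ccl4 by 4.69 and Cxcl2 by 4.22. Glucocorticoid response genes had 11 of 15 rising, or 13 adjusted over the list alone (median 1.87, fry adjusted p = 4.09e-06), with Mt2 up by 3.79 and Errfi1 by 3.23. Immediate early genes had 11 of 17 rising, and 11 adjusted over the list alone (median 1.54, fry adjusted p = 0.000776, adjusted p = 0.129 with an estimated correlation), with Atf3 up by 4.06 ± 0.68, Ier3 by 3.79 and Jun by 2.81 ± 0.35. Macrophage genes had 8 of 17 rising, or 9 adjusted over the list alone (median 0.70, fry adjusted p = 0.000175), and neutrophil genes 6 rising, or 11 (median 1.12, fry adjusted p = 0.000378). Both had adjusted p = 0.0743 with an estimated correlation. Spic, which specifies red pulp macrophages, rose by 2.69 ± 0.23 and Cxcr2 by 1.36. The YAP target list of 10 had 5 rising, or 7 adjusted over the list alone, with Ctgf at 3.03 (median 1.64, fry adjusted p = 0.000212, adjusted p = 0.073 with an estimated correlation).

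Proliferation and thymocyte genes fell in thymus over 1 to 8 h. The S phase list had 19 of 28 falling, or 26 adjusted over the list alone (median -1.08, fry adjusted p = 0.000212, adjusted p = 0.05004 with an estimated correlation), with Mcm2 at -1.89 ± 0.30 and Mcm6 at -1.63. The G2 and M list had 17 falling, or 26 adjusted over the list alone (median -1.22, fry adjusted p = 0.00298, adjusted p = 0.121 with an estimated correlation), with Ccnb1 at -2.03 ± 0.39 and Plk1 at -1.98 ± 0.32. DNA repair and checkpoint genes had 9 of 28 falling, or 11 adjusted over the list alone (median -0.55, fry adjusted p = 0.000175), with H2afx at -1.69 and Parp1 at -1.13. T cell genes had 6 falling, or 8 adjusted over the list alone, with Cd5 at -1.46 and Lef1 at -1.30 (median -0.69, fry adjusted p = 0.000326, adjusted p = 0.05004 with an estimated correlation). Genes of double positive thymocytes had 3 of 13 falling, or 6 adjusted over the list alone, with Dntt at -0.93 ± 0.17 (median -0.50, fry adjusted p = 0.00398, adjusted p = 0.135 with an estimated correlation). Cdca7 fell by 2.33 ± 0.39. In all 1508 of 12426 genes changed, 1024 up and 484 down, a rising share of 67.9%, and 52.6% after quantile normalization. The count was 760 with a 2-fold threshold and 6050 with a spline over time.

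Between 1 to 5 h and 6 to 8 h in thymus, all 28 S phase genes fell (median -1.59, fry adjusted p = 7.4e-08, adjusted p = 0.0758 with an estimated correlation), also adjusted over the list alone. Ccne2, which encodes cyclin E2, fell by 2.84 ± 0.38 (adjusted p = 5.73e-06), the origin recognition gene Orc6 by 2.66 (listed near 0 at 8 h), Gins1 by 2.02, Dtl by 2.01, and the replication clamp gene Pcna by 1.73 ± 0.19. DNA repair and checkpoint genes had 22 of 28 falling, or 23 adjusted over the list alone (median -0.70, fry adjusted p = 5.63e-08, adjusted p = 0.0502 with an estimated correlation), with the checkpoint kinase gene Chek1 at -1.66 and Brca1 at -1.46. The G2 and M list had 13 falling, or 14 adjusted over the list alone, with Bub1 at -1.18 (median -0.65, fry adjusted p = 0.0305, adjusted p = 0.508 with an estimated correlation). Double positive thymocyte genes had 10 of 13 falling, or 12 adjusted over the list alone (median -0.72, fry adjusted p = 1.82e-07, adjusted p = 0.0758 with an estimated correlation), with Dntt at -1.16 ± 0.12 and Rag1 at -0.78 ± 0.11. T cell genes had 11 falling, or 13 adjusted over the list alone, with Cd28 at -0.84 (median -0.67, fry adjusted p = 4.09e-05, adjusted p = 0.15 with an estimated correlation). Psmb11, a gene of cortical thymic epithelium, fell by 2.68 ± 0.21 (adjusted p = 2.09e-08), from 22.1 FPKM at 0 h to 1.32 at 6 to 8 h.

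Inflammatory genes rose in thymus at 6 to 8 h. Mt2 rose by 3.88 ± 0.56 (adjusted p = 1.3e-05) to 1730 FPKM, Slfn4 by 3.82 ± 0.42, Timp1 by 3.61, F3 by 3.61 and Ptx3 by 3.60 (listed near 0 at 1 h). The NF-kB list had 19 of 20 rising, and 19 adjusted over the list alone (median 1.60, fry adjusted p = 1.16e-06, adjusted p = 0.0904 with an estimated correlation), with Cxcl1 up by 3.25 and Relb by 1.03. Neutrophil genes had 11 rising, or 12 adjusted over the list alone, with Cxcr2 up by 2.56 (median 1.66, fry adjusted p = 1.07e-07, adjusted p = 0.0758 with an estimated correlation). Interferon response genes had 22 rising, or 25 adjusted over the list alone (median 1.2, fry adjusted p = 0.00138, adjusted p = 0.502 with an estimated correlation), with Rsad2 up by 2.43 and Cxcl10 by 1.83. The YAP target list had 8 rising, and 8 adjusted over the list alone (median 1.45, fry adjusted p = 4.09e-05, adjusted p = 0.253 with an estimated correlation). Thymic epithelium genes had 5 of 11 rising and 2 falling, as adjusted over the list alone, with Foxn1 up by 1.43 (listed near 0 at 5 h), Epcam by 1.29 and Krt5 by 0.81 (median 0.18, fry adjusted p = 0.00283, adjusted p = 0.502 with an estimated correlation), and a median of 0.03 with fry adjusted p = 0.121 after quantile normalization. Among p53 targets, the list had 10 members up and 6 down (median 0.07, fry adjusted p = 0.688), with Cdkn1a up by 0.84 ± 0.25 and Trp53inp1 down at -0.60. Its median was -0.02 without the 1 h library and -0.08 after quantile normalization. In all 3986 genes changed, 2316 up and 1670 down, a rising share of 58.1%, and 46.5% after quantile normalization.

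At 24 h in thymus, thymocyte genes were far below 0 h. Rag1, the recombinase of antigen receptor genes, went from 314 to 2.27 FPKM (-6.59 ± 0.21, adjusted p = 1.06e-16). Dntt changed by -6.78 ± 0.22 and Rag2 by -5.30 ± 0.17 with the same adjusted p, and the lineage genes Bcl11b, Tcf7 and Cd8b1 by -3.76, -4.09 and -4.86. Of 13 double positive thymocyte genes 12 fell (median -4.18, percentile 0, fry adjusted p = 2.04e-15), and of 18 T cell genes all fell (median -2.77, percentile 0, fry adjusted p = 4.47e-11). The list of S phase genes had 27 of 28 falling (median -2.68, fry adjusted p = 1.92e-07, adjusted p = 0.0984 with an estimated correlation), and the G2 and M list had 29 falling and 1 rising (median -3.35, fry adjusted p = 3.08e-06, adjusted p = 0.199 with an estimated correlation). Adjusted over the list alone, the counts of these 4 lists were the same. Rrm2 changed by -4.45, Plk1 by -3.95 and Clspn by -3.77. Trp53 was lower (-1.69 ± 0.24, adjusted p = 6.82e-06).

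Macrophage and interferon genes were higher at 24 h in thymus. Macrophage genes had 15 rising, and adjusted over the list alone 15 rose and 1 fell (median 1.67, percentile 100, fry adjusted p = 5.07e-06, adjusted p = 0.305 with an estimated correlation), with Cd68 up by 2.40 and C1qb by 1.98. All 26 interferon response genes rose, also adjusted over the list alone (median 2.85, percentile 100, fry adjusted p = 6.87e-05, adjusted p = 0.397 with an estimated correlation), with Irf7 up by 3.26 and Bst2 by 3.01. Among p53 targets, the list had 28 rising and 5 falling, or 29 and 5 adjusted over the list alone (median 0.93, percentile 100, fry adjusted p = 0.00072, adjusted p = 0.574 with an estimated correlation), with Cdkn1a up by 4.18 ± 0.47 (adjusted p = 3.22e-07), Ccng1 by 2.77 and Bbc3 by 0.87. The p53 apoptosis list had 11 rising and 2 falling members, as adjusted over the list alone (median 0.92, fry adjusted p = 0.00171, adjusted p = 0.574 with an estimated correlation), and a median of 0.48 with fry adjusted p = 0.0603 after quantile normalization.

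Genes of gut epithelium stood out in the same 24 h thymus library, the library with small intestine transcripts. All 14 enterocyte genes rose (median 7.62, percentile 100, fry adjusted p = 1.55e-05, adjusted p = 0.397 with an estimated correlation), as did all 9 goblet cell genes (median 6.0, fry adjusted p = 9.45e-14), all 9 Paneth cell genes (median 5.47, fry adjusted p = 0.00382, adjusted p = 0.574 with an estimated correlation) and 8 of 9 colonocyte genes (median 3.64, fry adjusted p = 1.88e-12), with the same counts adjusted over the list alone. Defa24, an antimicrobial peptide gene, changed by 11.20 ± 2.66 (adjusted p = 0.00157), Fabp2 by 10.57 ± 1.57, the mucus gene Zg16 by 10.34, Rbp2 by 10.27, Tff3 by 8.66, Vil1 by 7.33, Agr2 by 6.30 ± 0.26 and Muc2 by 4.72. Thymic epithelium genes had 5 rising and 2 falling, as adjusted over the list alone, with Prss16 at -1.11 (median 0.64, percentile 80.3, fry adjusted p = 0.00031, adjusted p = 0.574 with an estimated correlation), and a median of 0.22 with fry adjusted p = 0.318 after quantile normalization.

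In all 5585 genes changed at 24 h in thymus, 3275 up and 2310 down, a rising share of 58.6%, and 42.5% after quantile normalization, which moved the median of all genes from 0.15 to -0.12. With the small intestine share subtracted, 5266 genes changed, a fit chosen after the data were seen.

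**Figure D4:**
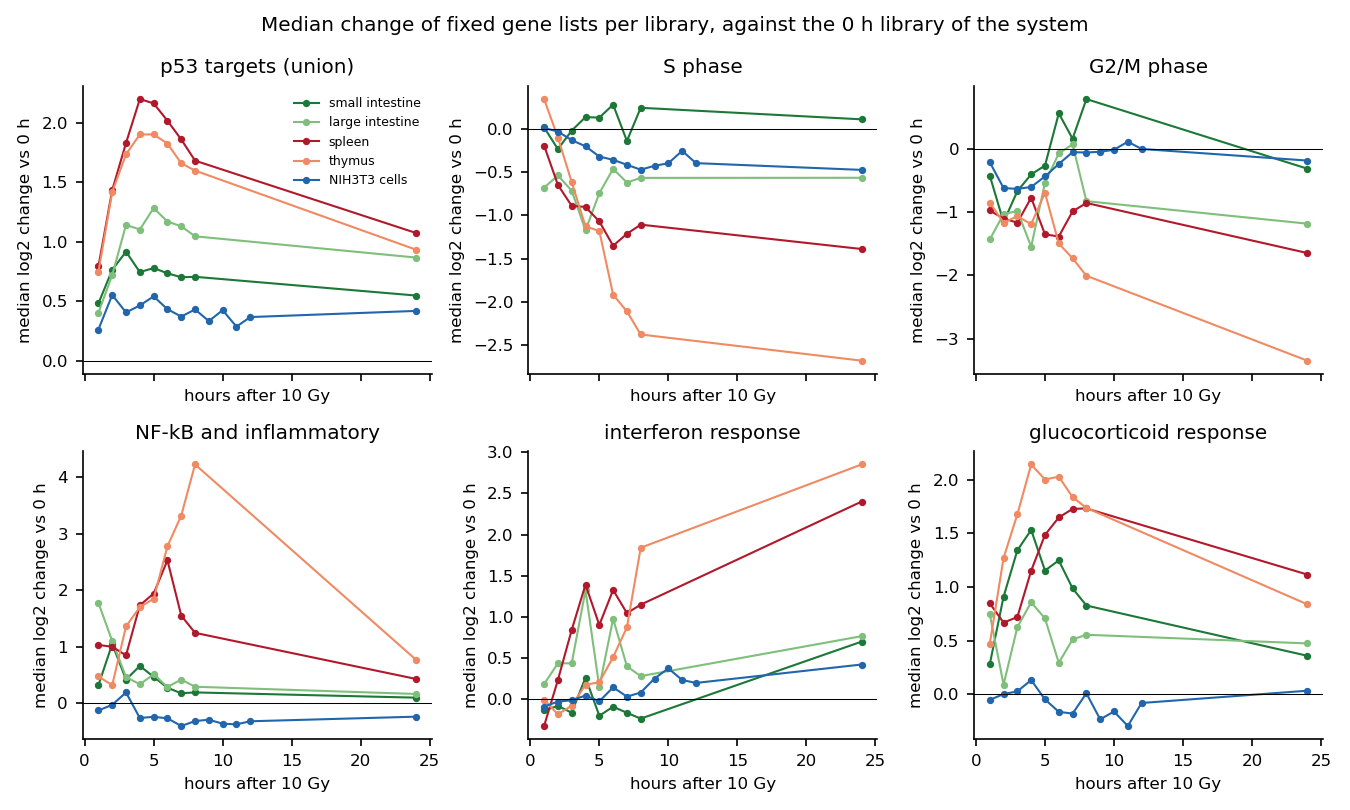
Lines give the median log2 change against the 0 h library of the p53 target, S phase, G2 and M, NF-kB, interferon and glucocorticoid lists in each library, by hours after irradiation and system. In thymus at 24 h the S phase median is -2.68 and the interferon median 2.85.

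Spleen and thymus differed from the intestines in their p53 response. Over 1 to 8 h and on the log2 scale, Cdkn1a rose more in the lymphoid tissues, by 3.59 ± 0.36 (adjusted p = 5.4e-06), though it gained 258 FPKM in the intestines and 224 in the lymphoid tissues. Bbc3 rose more by 2.36 ± 0.25 (adjusted p = 1.34e-05), Gdf15 by 2.89, the death receptor gene Tnfrsf10b by 1.83, Sesn2 by 1.58 ± 0.24, Ei24 by 1.5, Zmat3 by 1.31 and Fas by 1.2. Dgka had a difference of -0.69 (adjusted p = 0.0129). The differences of Pmaip1 (1.31, adjusted p = 0.0653), Bax (0.81, adjusted p = 0.0911), Mdm2 (0.59, adjusted p = 0.106), Ccng1 (0.35, adjusted p = 0.453), Phlda3 (0.20, adjusted p = 0.818), Eda2r (-0.80, adjusted p = 0.217) and Trp53inp1 (adjusted p = 0.997) did not pass. Of 51 p53 targets, 14 rose more and 1 less, or 21 and 3 adjusted over the list alone (median 0.67, fry adjusted p = 0.0249, adjusted p = 0.277 with an estimated correlation). With other window borders, fry gave adjusted p = 0.0819. The arrest list had 5 higher members, or 8 adjusted over the list alone (median 0.93, fry adjusted p = 0.0144), and the apoptosis list 6 higher and 1 lower, or 11 and 3 (median 0.72, fry adjusted p = 0.0249). Both had adjusted p = 0.277 with an estimated correlation.

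S phase genes differed by a median of -0.75 over 1 to 8 h, with 1 member lower over all genes and 15 adjusted over the list alone (fry adjusted p = 0.0249, adjusted p = 0.277 with an estimated correlation). In all 277 of 9980 genes differed, 192 upward and 85 downward. The rising share was 69.3%, and 58.0% after quantile normalization. The count was 542 without the 2 h large intestine library, 472 without its 1 h library and 428 without the 2 h large intestine and 6 h spleen libraries. It was 450 with no filter and 106 with other window borders.

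From 1 to 5 h to 6 to 8 h, proliferation genes went apart between lymphoid and intestinal tissue. The G2 and M list differed by -1.41, with 26 members lower, also adjusted over the list alone (fry adjusted p = 7.91e-05, adjusted p = 0.234 with an estimated correlation). Kif11 differed by -1.65 and Top2a by -1.64. The list of S phase genes had 23 members lower, or 24 adjusted over the list alone (median -1.19, fry adjusted p = 6.48e-06, adjusted p = 0.166 with an estimated correlation), with Mcm5 at -1.71 and Fen1 at -1.19. DNA repair and checkpoint genes had 16 lower, or 17 adjusted over the list alone (median -0.70, fry adjusted p = 6.6e-08). With the same counts adjusted over the list alone, NF-kB genes (6 higher, median 0.74, fry adjusted p = 7.91e-05, adjusted p = 0.234 with an estimated correlation) and interferon genes (15 higher, median 0.89, fry adjusted p = 0.00565, adjusted p = 0.413 with an estimated correlation) moved upward, with Bcl3 at 2.58 and Cxcl10 at 2.45. Ccng1 fell in lymphoid tissue relative to intestine (-0.80 ± 0.15, adjusted p = 0.000531) and Plk3 rose (1.36), with a p53 list median of -0.18 (fry adjusted p = 0.484). In all 2936 genes differed, 1654 upward and 1282 downward (56.3% rising, 42.4% after quantile normalization).

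At 24 h against 0 h, Cdkn1a was higher in lymphoid than in intestinal tissue by 3.89 ± 0.47 (adjusted p = 9.73e-06), Pmaip1 by 1.75, Casp1 by 2.12 and Sesn2 by 1.09. Trp53 (-1.45 ± 0.24, adjusted p = 0.000199) and the p53 target Btg2 (-1.63) moved the other way. Among p53 targets, the list had a median of 0.15 (fry adjusted p = 0.742), and -0.17 after quantile normalization. S phase genes had 23 members lower, also adjusted over the list alone (median -1.76, fry adjusted p = 0.000126, adjusted p = 0.265 with an estimated correlation). The G2 and M list had 22 lower and 1 higher, or 24 and 1 adjusted over the list alone (median -1.83, fry adjusted p = 0.00432, adjusted p = 0.494 with an estimated correlation). Macrophage genes had 10 higher, or 11 adjusted over the list alone (median 1.65, fry adjusted p = 6.75e-05, adjusted p = 0.265 with an estimated correlation). Interferon genes had 14 higher, or 16 adjusted over the list alone (median 1.68, fry adjusted p = 0.00995, adjusted p = 0.521 with an estimated correlation), with Cxcl10 at 3.16 and Irf7 at 2.21. In all 2724 genes differed, 1607 upward and 1117 downward (59.0% rising, 39.5% after quantile normalization).

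In NIH3T3 over 1 to 8 h, p53 targets rose. Trp53inp1 rose by 1.76 ± 0.15 (adjusted p = 4.51e-05), Cdkn1a by 1.12 ± 0.12 (adjusted p = 0.000488), Eda2r by 1.13, Pmaip1 by 1.1, Sesn2 by 1.08, Bbc3 by 1.05 ± 0.17, Pidd1 by 1.05, Ccng1 by 0.94 and Mdm2 by 0.94 ± 0.14 (adjusted p = 0.00723). Mdm2 stood at 30.2 FPKM at 0 h, 96.7 ± 2.1 at 1 to 2 h (SD, n = 2) and 51.5 ± 7.4 at 3 to 5 h (SD, n = 3). Bax (-0.02, adjusted p = 0.921) and Phlda3 (0.36, adjusted p = 0.125) did not pass. Of 47 p53 targets 15 rose, or 24 adjusted over the list alone (median 0.43, fry adjusted p = 0.00392, adjusted p = 0.155 with an estimated correlation), and the arrest list of 18 had 7 rising, or 10 adjusted over the list alone (median 0.51, fry adjusted p = 0.000132).

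The S phase list was lower in NIH3T3 (median -0.25, 3 falling, 8 adjusted over the list alone, fry adjusted p = 0.0367, adjusted p = 0.315 with an estimated correlation), with Ccne1 at -0.65 and Mcm6 at -0.41. The G2 and M list had 5 falling, or 12 adjusted over the list alone (median -0.33, fry adjusted p = 0.0494, adjusted p = 0.316 with an estimated correlation), with Ccnb2 at -0.64 and Cenpa at -0.54. After quantile normalization neither was called, and the S phase median was -0.14 with fry adjusted p = 0.12. Median-of-ratios scaling also ended the G2 and M call (fry adjusted p = 0.0565). The YAP target gene Ctgf fell by 1.03 ± 0.26 and Angptl4 by 0.87. The transcription factor gene Tead4 rose by 1.91 ± 0.18 (adjusted p = 0.000158). Pard6a (2.47), Whrn (2.31), Taf1a (2.28), Mapk1ip1 (2.11) and Ccdc130 (2.11) were listed near 0 at 0 h.

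In NIH3T3 464 of 10385 genes changed over 1 to 8 h, 287 up and 177 down. The rising share was 61.9%, and 89.4% of 151 genes after quantile normalization. The count was 210 without the 7 h library. It was 298 with no filter, 295 with a robust prior variance and 49 with a 2-fold threshold.

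Between 1 to 5 h and 6 to 8 h in NIH3T3, mitotic genes rose and S phase genes fell. Plk1 rose by 0.85 ± 0.18 (adjusted p = 0.0328), Pif1 by 0.86 and Aurka by 0.72, and 6 G2 and M genes rose, or 21 adjusted over the list alone (median 0.35, fry adjusted p = 0.0395, adjusted p = 0.296 with an estimated correlation). Ccne2 fell by 1.18 ± 0.17 (adjusted p = 0.0125), Pcna by 0.50 and Mcm6 by 0.49, and 7 S phase genes fell, or 19 adjusted over the list alone (median -0.24, fry adjusted p = 0.00491, adjusted p = 0.178 with an estimated correlation). Interferon genes had 1 rising member, and 1 adjusted over the list alone (median 0.17, fry adjusted p = 0.00283, adjusted p = 0.178 with an estimated correlation). Mdm2 fell by 0.44 ± 0.10 and Nr4a1 by 1.2, and the clock gene Dbp rose by 0.79. The p53 list had a median of -0.08 (fry adjusted p = 0.409), which was -0.10 without the 1 h library (fry adjusted p = 0.027) and 0.0069 without that of 2 h.

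In all 239 genes changed between these windows in NIH3T3, 89 up and 150 down, a rising share of 37.2%, and 50.0% after quantile normalization. By limma the count was 0 without the 8 h library and 24 without that of 7 h. It was 469 without that of 5 h, 113 with no filter and 139 with a robust prior variance.

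By 9 to 12 h, several p53 targets had fallen from 1 to 5 h in NIH3T3. Mdm2 fell by 0.65 ± 0.09 (adjusted p = 0.00124), Eda2r by 0.65, Pmaip1 by 0.50, Bbc3 by 0.47, Trp53inp1 by 0.42, Phlda3 by 0.40, Cdkn1a by 0.29 ± 0.08 (adjusted p = 0.0257) and Trp53 by 0.25. The p53 apoptosis list had 9 falling members, and adjusted over the list alone 10 fell and 1 rose (median -0.30, adjusted p = 0.254 with an estimated correlation). The arrest list had 6 falling, or 7 adjusted over the list alone (median -0.20, adjusted p = 0.188 with an estimated correlation). Both had fry adjusted p = 0.0153, while the union, with 14 falling and 2 rising, had a median of -0.16 (fry adjusted p = 0.0822). G2 and M genes had 22 rising, or 25 adjusted over the list alone (median 0.50, fry adjusted p = 0.00187), with Aurka up by 0.91 and Ube2c by 0.78, and S phase genes 13 falling, or 14 adjusted over the list alone (median -0.23, fry adjusted p = 0.00187), with Ccne2 at -1.27 ± 0.16. Both had adjusted p = 0.15 with an estimated correlation.

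Interferon genes had 5 rising at 9 to 12 h in NIH3T3, or 7 adjusted over the list alone, with Stat2 up by 0.38 (median 0.29, fry adjusted p = 6.63e-05, adjusted p = 0.0872 with an estimated correlation). Fibroblast genes had 6 rising, or 7 adjusted over the list alone (median 0.31, fry adjusted p = 0.00187, adjusted p = 0.15 with an estimated correlation). Cholesterol synthesis genes had 7 falling, or 8 adjusted over the list alone, with Lss at -0.38 (median -0.17, fry adjusted p = 0.0177, adjusted p = 0.281 with an estimated correlation). NF-kB genes had 5 falling, or 6 adjusted over the list alone, with Cxcl1 at -1.09 (median -0.22, fry adjusted p = 0.0344, adjusted p = 0.323 with an estimated correlation). Ereg fell by 1.12 and Egr1 by 1.04, while Sdf2l1 and Prelp rose by 1.03 each. In all 1408 genes changed, 731 up and 677 down, and the count was 820 without the 10 h library and 922 without that of 12 h.

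Pulses of p53 are known from cultured cells. By limma 0 of 10385 genes had a rhythm with a period of 5 h over 1 to 12 h, with 328 at an unadjusted p below 0.05. Of the 47 p53 targets 5 had an unadjusted p below 0.05, and 0 passed when adjusted over the list alone. The counts were 0 for periods of 4 h and 6 h as well, and 1 for 5 h without the 1 h library. Simulation recovered 87% of genes at a log2 amplitude of 0.5, but p53 targets reached at most 0.32 (Fas), so smaller pulses stay open.

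At 24 h in NIH3T3, matrix genes were higher. Col3a1, a fibrillar collagen gene, rose by 2.03 ± 0.19 (adjusted p = 7.6e-05), from 27.3 to 115 FPKM, Lum by 1.69 and Dcn by 1.30. Of 10 fibroblast genes 8 rose, or 9 adjusted over the list alone (median 0.95, percentile 100, fry adjusted p = 0.000187, adjusted p = 0.0704 with an estimated correlation). S phase genes had 15 falling, or 18 adjusted over the list alone (median -0.47, percentile 0, fry adjusted p = 0.00125), and interferon genes 2 rising, and 2 adjusted over the list alone (median 0.42, percentile 97.9, fry adjusted p = 0.000518). Both had adjusted p = 0.115 with an estimated correlation. Ccne2 was lower (-2.21 ± 0.33, adjusted p = 0.0017), as were Rrm2 (-1.01), Ctgf (-1.87), Fxyd5 (-1.72 ± 0.20) and Akr1c18 (-2.09). Trp53inp1 was higher by 1.68, Btg2 by 1.45, Bbc3 by 1.22, Cdkn1a by 1.18 ± 0.16 and Ccng1 by 0.86, while Mdm2 had 0.39 (adjusted p = 0.198). The p53 list had 11 rising members, or 13 adjusted over the list alone (median 0.42, percentile 100, fry adjusted p = 0.0139, adjusted p = 0.262 with an estimated correlation). In all 1147 genes changed, 586 up and 561 down.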

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

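The tests of small intestine RNA in the thymus library and of the p53 difference between tissues were chosen after the results were seen. Some replaced a first version that had not decided or was void. For a wrong label, the first was the difference of median correlations with thymus (0.778) and small intestine libraries (0.760), which was 0.0177. For shallow libraries, it was the share of cases at genes with a median of at least 10 FPKM, 11.4% (exact 95% interval 7.83% to 15.9%). For the p53 difference, the first versions gave 0.69 after median-of-ratios scaling, which hardly moved values, 0.63 without the 2 h large intestine and 6 h spleen libraries, a median log2 ratio of gains of 1.37 over 42 genes with a gain in both, and a larger lymphoid gain in 70.6% of all 51.

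Gut transcripts in the 24 h thymus library came with a loss of thymocyte genes. Of 312 small intestine genes, 86.9% stood within 2-fold of a common ratio to the 24 h small intestine library, as RNA of that organ in the library needs. Their median level was 11.2% of that library, far below what a small intestine library under a thymus label needs, and the thymic epithelium list had a median of 0.64 against over 7 for enterocyte genes, which speaks against a larger share of thymic epithelium. Admixed small intestine RNA is a candidate explanation, and whether it entered at dissection or at library preparation was not tested. Rag1 at 2.27 FPKM is far below the 0 h level of 314, more than an admixture of this share would lower it.

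Some genes stood below 0.05 FPKM in 1 library, at 1 or more in the next lowest and at a median of at least 2 in the same system, in 263 cases of 230 genes. They overlapped another annotated gene as often as other genes (45.9% against 46.0%, odds ratio 0.996, 95% interval 0.758 to 1.30), and 9.51% of the cases lay at 0 h, where 9.26% of the libraries lie, so neither failed estimates at overlapping genes nor transcripts absent before irradiation account for them. Libraries under their system's median relative depth (50.0% of all) held 69.6% of cases (exact 95% interval 63.6% to 75.1%). Too few fragments in shallow libraries may contribute. This stays open, as depths are rough, the interval spans the set 70% bound and falling genes (Klf1, 24 h spleen) are included.

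On the log2 scale p53 targets rose more in lymphoid than in intestinal tissue, by a median of 0.67. This difference stood 0.67 above the median of all genes (0.003), which argues only against a scaling shift common to all. It was 0.68 against small intestine alone without the 6 h spleen library (95% interval over genes 0.42 to 0.96). This argues against admixed RNA as the whole cause. A higher 0 h level in the intestines stays open. Of the 24 genes with one, 66.7% gained more FPKM in lymphoid tissue (exact 95% interval 44.7% to 84.4%). Their median difference was 1.18, and 0.46 (-0.19 to 0.81) in the other 27. Cdkn1a, at 184 FPKM at 0 h in the intestines and 7.16 in lymphoid tissue, gained more in the intestines (258 against 224), as did Pmaip1, Perp, Eda2r and Ephx1. A difference in cell composition was not tested, and adjusted p was 0.277 with an estimated correlation.

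Lymphoid and intestinal tissue differed by the test of the difference itself in 277 genes over 1 to 8 h, in 2936 between 1 to 5 h and 6 to 8 h, and in 2724 at 24 h. Over 1 to 8 h the called lists besides p53 had medians of -0.75 (S phase), 0.66 (glucocorticoid), 0.27 (clock), 0.51 (macrophage), 0.27 (thymic epithelium) and 0.44 (intestinal stem cell). The calls of the glucocorticoid, clock, macrophage and stem cell lists ended after quantile normalization. At 6 to 8 h they had -0.70 (DNA repair), -1.19 (S phase), -1.41 (G2 and M), 0.79 (immediate early), 0.40 (heat shock), 0.57 (glucocorticoid), 0.89 (interferon), 0.74 (NF-kB), -0.41 (B cell), -0.56 (T cell), 0.63 (macrophage), 0.77 (plasma cell), 0.44 (thymic epithelium) and 0.97 (YAP targets). At 24 h they had -0.69 (DNA repair), -1.76 (S phase), -1.83 (G2 and M), 0.95 (clock), 1.68 (interferon), -1.85 (T cell), -2.83 (erythroid), 1.65 (macrophage), 1.42 (thymic epithelium), 3.50 (Paneth cell), 1.57 (YAP targets), 1.57 (smooth muscle) and 1.53 (fibroblast). The calls of the thymic epithelium, Paneth cell, YAP, smooth muscle and fibroblast lists at 24 h ended after quantile normalization. The Paneth cell value moves with the 24 h thymus library. Of the called lists, with the p53 arrest and apoptosis lists, 0 of 8 over 1 to 8 h, 1 of 14 at 6 to 8 h and 0 of 13 at 24 h held with an estimated correlation.

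By the fixed rule, the genes that differed most over 1 to 8 h were Cdkn1a (3.59), Cyr61 (3.52), Ccl12 (3.25), Ccl2 (3.18), Tgfb1i1 (2.98), Crlf2 (-2.35), Kbtbd4 (-1.87), Pars2 (-1.87), Chp2 (-1.75) and Cpsf1 (-1.60). At 6 to 8 h they were Slfn4 (4.28), Mt2 (3.98), Mt1 (3.14), Ccr1 (3.0), Il33 (2.96), Mettl5 (-2.21), Orc6 (-2.08), Ccna2 (-1.93), Nmral1 (-1.92) and Cenpk (-1.78). At 24 h they were Slfn4 (5.42), Lgals2 (4.82), Ces2e (4.43), Ccl12 (4.33), Sct (4.22), Hbb-bt (-4.15), Crlf2 (-3.74), Rrm2 (-3.40), Syce2 (-3.36) and Cdca7 (-3.32), of which Lgals2, Ces2e and Sct move with the thymus library that held gut transcripts. Of these genes, Crlf2, Cpsf1, Kbtbd4, Pars2, Ccl12, Tgfb1i1, Mettl5, Orc6, Nmral1, Sct, Hbb-bt and Syce2 were listed near 0 in a library of a tissue. In NIH3T3 at 9 to 12 h, the 12 h library lay far from the others for Mdm2 (36.4 FPKM against 43.5 to 44.3) and for the mean log2 level of the fibroblast list (6.08 against 5.87 to 5.90), 2 of 34 values examined, where chance gives about 1 in 20.

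At 6 to 8 h, 66 genes changed in small intestine, 3263 in spleen, 3986 in thymus and 239 in NIH3T3. As many came from 2, 2, 1 and 2 of 56 splits of the same libraries, the real split included. The highest other counts were 128, 3375, 3921 and 534, all from setting hours 1 to 3 apart. A steady change with time favours such blocks of hours, so these counts cannot exclude chance. In large intestine 12 of 56 splits gave at least the 64 genes, up to 543, so chance stays open too. Only there did mixed hours exceed the real count (510 for 2, 4 and 8 h), which points to another structure of the samples. For 9 to 12 h in NIH3T3 (1408 against 1043 at most) and for lymphoid minus intestinal tissue at 6 to 8 h (2936 against 2434), 1 of 100 splits gave as many. For 1 to 8 h against 0 h only 9 libraries can take the place of 0 h, too few for a share under 0.05. With the 0 h library included, as many genes came from 3 of them in small intestine (36, highest other 59), 3 in large intestine (179, 1864), 1 in spleen (1015, 674), 3 in thymus (1508, 2344) and 1 in NIH3T3 (464, 39).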

How the results depend on the processing

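The fits without libraries holding transcripts of another organ, with the small intestine share subtracted and without genes listed near 0 were chosen after seeing the data. The counts and p53 medians compared kept their direction and their side of the threshold, with counts within 1.5 times, under median-of-ratios scaling (38 results, other list calls aside), without the 24 h libraries (25) and with the small intestine share subtracted (4, thymus 24 h 5266, lymphoid minus intestinal 2602). Correlations between tissues for libraries of the same number had a median of 0.0408 (5 of 48 above 0.1), and whether organs of 1 hour share a mouse is not given in the sources used here. With time point as a replicate block (correlation 0.0202) all 30 results stayed, with 5599 genes for thymus at 24 h.

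Elsewhere the following values differed, and the cause was not tested unless named. A pseudocount of 0.1 gave 57 and 46 genes in small intestine at 1 to 8 h and 24 h and 6 in large intestine at 6 to 8 h. With no filter, which tests more genes, lymphoid minus intestinal 1 to 8 h had 450, and NIH3T3 298 at 1 to 8 h and 113 at 6 to 8 h. Quantile normalization gave 151 in NIH3T3 at 1 to 8 h, and turned the p53 medians of thymus at 6 to 8 h (-0.082) and of lymphoid minus intestinal at 24 h (-0.17). A robust prior gave 295 and 139 in NIH3T3 at 1 to 8 h and 6 to 8 h. Separate fits, with fewer libraries behind each spread, gave 20, 5 and 10 in small intestine for 1 to 8 h, 6 to 8 h and 24 h, 17, 0 and 2 in large intestine, and 546 in spleen at 1 to 8 h. Other window borders gave 23 and 13 in small intestine at 1 to 8 h and 24 h, 88 and 16 in large intestine at 1 to 8 h and 6 to 8 h, and 106 for lymphoid minus intestinal at 1 to 8 h. They ended the calls of the p53 list in large intestine at 24 h (0.87, fry adjusted p = 0.0688) and in lymphoid minus intestinal tissue at 1 to 8 h (0.67, fry adjusted p = 0.0819). A 2-fold threshold, stricter by construction, gave 118 in large intestine, 502 in spleen, 760 in thymus and 49 in NIH3T3 at 1 to 8 h. A spline gave 1 in large intestine, 4099 in spleen and 6050 in thymus. Without the 2 h large intestine and 6 h spleen libraries, small intestine at 6 to 8 h had 138, large intestine 506 at 1 to 8 h and 95 at 24 h, and lymphoid minus intestinal 1 to 8 h 428. Without the 24 h thymus library as well, these were 138, 506, 95 and 427. Without genes listed near 0, small intestine at 24 h had 13.

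Leaving out each irradiated library in turn, counts ranged from 30 to 42, 2 to 184 and 16 to 23 in small intestine for 1 to 8 h, 6 to 8 h and 24 h, and from 126 to 508, 21 to 531 and 29 to 91 in large intestine. They ranged from 791 to 1321, 2123 to 4075 and 2321 to 2590 in spleen, 1074 to 2087, 2704 to 4176 and 5469 to 5625 in thymus, and 210 to 591, 0 to 469 and 942 to 1209 in NIH3T3, where 9 to 12 h had 820 to 1573 and the rhythm 0 to 1. For lymphoid minus intestinal they were 195 to 542, 2611 to 3475 and 2603 to 3222. Medians of p53 targets at 1 to 8 h and 6 to 8 h were 0.64 to 0.80 and -0.12 to -0.03 in small intestine, 1.013 to 1.15 and 0.011 to 0.20 in large intestine, 1.64 to 1.92 and -0.32 to -0.054 in spleen, 1.51 to 1.72 and -0.024 to 0.15 in thymus, 0.39 to 0.44 and -0.12 to 0.0069 in NIH3T3, and 0.60 to 0.75 and -0.21 to -0.09 for lymphoid minus intestinal. At 6 to 8 h the sign turned in thymus without the 1 h library (-0.024) and in NIH3T3 without the 2 h library (0.0069), and the list was called in spleen (-0.32) and NIH3T3 (-0.10) without the 1 h library.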

Other observations

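Several lists not described above moved in thymus and spleen. In thymus B cell markers fell over 1 to 8 h, with 7 of 14 past the threshold, or 9 adjusted over the list alone (median -1.03, fry adjusted p = 0.000673, adjusted p = 0.0743 with an estimated correlation). At 6 to 8 h in thymus, smooth muscle genes had 7 of 11 rising (median 0.66, fry adjusted p = 0.0074) and endothelial genes 6 of 9 (median 0.67, fry adjusted p = 0.00563), both with adjusted p = 0.508 with an estimated correlation. In spleen at 6 to 8 h DNA repair and checkpoint genes had 11 of 25 falling, or 12 adjusted over the list alone (median -0.37, fry adjusted p = 0.0012, adjusted p = 0.38 with an estimated correlation).

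At 24 h the interferon list stood at percentile 100 among random lists in small intestine (median 0.70) and large intestine (0.77, with 1.32 at 4 h) too, without a fry call. In small intestine the YAP target list also stood at percentile 100 (0.68, with 0.78 at 6 h), and the smooth muscle list (-1.07) at 0. At 0 also stood the adipocyte (-4.17), erythroid (-1.14) and Paneth cell (-0.54) lists, which were as low or lower at 7 h, 3 h and 2 h, in that order. In NIH3T3 the YAP target list stood at percentile 0 (median -0.71).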
